A study of Mus musculus with 12 samples.

How the data were processed

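RNA was sequenced from the subventricular zone of male wild-type mice, the tissue along the lateral ventricle that holds neural stem cells. Per the labels, the tissue was dissected and dissociated to single cells, and total RNA was isolated with Trizol. There were 12 libraries, 3 at each of 4 ages (2, 6, 18 and 22 months). The labels state that the ages were sampled in triplicate and do not state that the 3 libraries of an age came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. A strain (C57BL/6) is given for the 2-month samples alone. No sequencing date, lane or library batch is given.

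The authors deposited 1 table of signal values with 1 column per library, in which each value is a read count of a gene divided by a size factor of its library. This was tested on the values: with a tolerance of 1e-06, 100% of the values of each column were whole multiples of the column's smallest value, so the whole reads could be recovered. The submitters' notes name DESeq2 and the mouse build mm10. They do not state the aligner, the counting tool, the annotation, the strandedness or any version. Size factors estimated again from the recovered reads differed from the authors' by a spread of 2.28% at most. 1 further column, the authors' own comparison, was not used.

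The table held 23725 genes, of which 456 had no symbol and 27 had a symbol that a spreadsheet had turned into a date. These 27 genes were carried by their identifier, and 26 of them were tested. Identifiers were matched to RefSeq genes on GRCm38.p6, where 23666 were found, and symbols are printed as the table gives them. Transcript length and GC content came from another annotation, GENCODE, as those of the longest transcript of each gene. They were available for 14853 of the tested genes (94.8%). 2277 genes had no read in any library, and no mitochondrial genes were in the table.

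The recovered reads totalled 6381390 to 15962517 per library. The limit set by a count of 0, taken as 3 reads, lay between 1.74 and 4.41 normalised counts. The 10 most abundant genes took 3.62% to 4.12% of a library. Reads without molecular identifiers are not independent molecules, so these limits cover counting error only.

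The 15663 genes with at least 10 normalised counts in at least 3 libraries were tested. Values were taken as log2 of the normalised count plus 1, and all 12 libraries were fitted together with limma (eBayes with an intensity trend, prior degrees of freedom 8.96). All 6 pairs of ages were compared, and an F test covered the ages together. P-values were adjusted by Benjamini-Hochberg over all tested genes within a comparison, two-sided, with a threshold of 0.05. Genes that turned at 18 months passed the threshold both for 18 against 6 and for 22 against 18 months with opposite signs, and genes that turned at 6 months did so for the pair of steps around 6 months. Errors of log2 fold changes are standard errors from limma, and errors of means are standard deviations over 3 libraries.

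A set of 30 gene lists was fixed before the data were examined, as were the comparisons, the tests, the rule for naming genes and the alternatives, except where an alternative is said to be chosen after seeing the data. The lists cover quiescent neural stem cells and astrocytes, activated stem cells and transit-amplifying progenitors, proliferation, neuroblasts, ependymal cells, oligodendrocytes, oligodendrocyte precursors, microglia, activated microglia, T and B lymphocytes, interferon-stimulated genes, antigen presentation, complement, endothelium, pericytes with smooth muscle and fibroblasts, choroid plexus, striatal projection neurons, pan-neuronal genes, erythroid genes, immediate early genes, heat shock proteins, senescence, WNT, BMP and TGF-beta, Hedgehog and Notch, secreted growth factors, extracellular matrix, the respiratory chain, ribosomal proteins and cholesterol synthesis. Lists with at least 5 tested members (29 of 30) were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists within a comparison. Each call was also computed with a correlation estimated from the residuals. C1qa, C1qb and C1qc stood in both the microglia and the complement lists, Id2 and Id3 in both the quiescent and the BMP lists, and Notch1 in both the activated and the Notch lists.

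The rule for named genes took, for 6 against 2, 18 against 6, 22 against 18 and 22 against 2 months, up to 10 genes higher and up to 10 lower by fold change among those past the threshold whose 3 libraries at one age all lay above the 3 of the other. Gene models without a proper symbol were skipped. It also took up to 8 genes per direction of a turn, up to 4 members of each list with the smallest p in a comparison, and a fixed panel of 16 genes whatever their result. A few genes that the rule took are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

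The alternatives chosen before the data were examined were DESeq2 on the recovered reads, limma without an intensity trend, quantile normalisation, no filter, a mean of at least 50 normalised counts, pseudocounts of 0.25 and 8, a replicate block, fits of the libraries of the 2 ages alone, a fold change of at least 1.5, and leaving out each library in turn. 5 alternatives were chosen after seeing the data. These were edgeR on the recovered reads, removal of a smooth trend over transcript length and GC content from each library (natural splines with 4 degrees of freedom each), the genes with a transcript length alone without that removal, reads thinned to the smallest library, and a fit without the 22-month libraries. The versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

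The design was tested on simulated data with 200 changed genes per comparison. At 1.5-fold, 84% to 90% of 100 changed genes were recovered, and at 2-fold, 93% to 99% of 100. The changed genes were drawn from those with a mean of at least 20 normalised counts. Each simulated gene had the spread smoothed over genes of its level. Recovery was therefore not measured for genes with lower counts or with a larger spread than others of their level. Between 1 and 19 unchanged genes were called, which was 0.549% to 9.5% of the calls. Of 20 simulated lists, the 5 raised by 1.3-fold were called and 0 of the others. The simulated genes varied independently, so this does not show how often lists whose members move together are called without an age effect.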

Results

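Transcripts of the mouse subventricular zone were measured at 2, 6, 18 and 22 months, with 3 libraries per age and 12 in all. The recovered reads totalled 7732316, 10112100 and 8541359 in replicates 1, 2 and 3 at 2 months and 9183822, 15962517 and 10513920 at 6 months. They totalled 10842864, 11476533 and 12991067 at 18 months and 7033545, 6381390 and 8992891 at 22 months. Correlations of log2 values ran from 0.984 to 0.994 between libraries of 1 age and from 0.969 to 0.991 between ages, across genes, which are not independent replicates. The share of reads on transcripts shorter than 1500 nt was 5.71% ± 0.176 at 2 months, 6.00% ± 0.332 at 6 months, 6.11% ± 0.309 at 18 months and 7.14% ± 0.049 at 22 months. The share on transcripts longer than 6000 nt was 24.9% ± 0.628, 24.3% ± 1.3, 24.3% ± 1.15 and 20.6% ± 0.25 in the same order. The comparisons ask which transcripts differed between ages and whether any changed course between them, as the study's title names non-monotonic change. Genes are given with their identifier (id) from the table where their position is given. Positions are RefSeq gene bounds on GRCm38.p6, and log2 fold changes are given with their standard errors (n = 3 against 3).

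A fixed panel of 16 genes was followed at every age. Mki67 (id17345, chromosome 7, 135689784 to 135716450), a nuclear protein of dividing cells, had normalised counts of 793 ± 36.9, 483 ± 156, 306 ± 51.3 and 194 ± 43.7 at 2, 6, 18 and 22 months (SD, n = 3). Dcx (id13193, chromosome X, 143855842 to 143933396), a microtubule protein of migrating young neurons, had 1136 ± 55.2, 740 ± 149, 580 ± 63.0 and 545 ± 88.6. Dlx2 (id13392, chromosome 2), a homeobox transcription factor of progenitors of interneurons, had 192 ± 29.7, 143 ± 25.6, 94.3 ± 19 and 114 ± 17.2. Gfap (id14580, chromosome 11), an astrocyte filament protein, had 1727 ± 228, 1480 ± 127, 2584 ± 591 and 2834 ± 436. C4b (id12268, chromosome 17), a complement component, had 557 ± 22.3, 813 ± 71.7, 1640 ± 361 and 1832 ± 295, and B2m (id12010, chromosome 2), the light chain of MHC class I, had 347 ± 45.8, 370 ± 48.6, 723 ± 164 and 1107 ± 592. Cx3cr1, a microglial chemokine receptor, had 560 ± 6.00, 557 ± 21.8, 660 ± 63.2 and 603 ± 32.6 and passed in none of the 6 comparisons. Mbp, a myelin protein, Ttr, the main secreted protein of the choroid plexus, and Cx3cr1 were the tested panel genes without a pass in any comparison. Cd3e, a T cell receptor subunit, and Cdkn2a, a cell cycle inhibitor, had means of at most 1.37 and 2.05 normalised counts, under the filter, so a difference was not detectable at this depth.

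**Figure D1:**
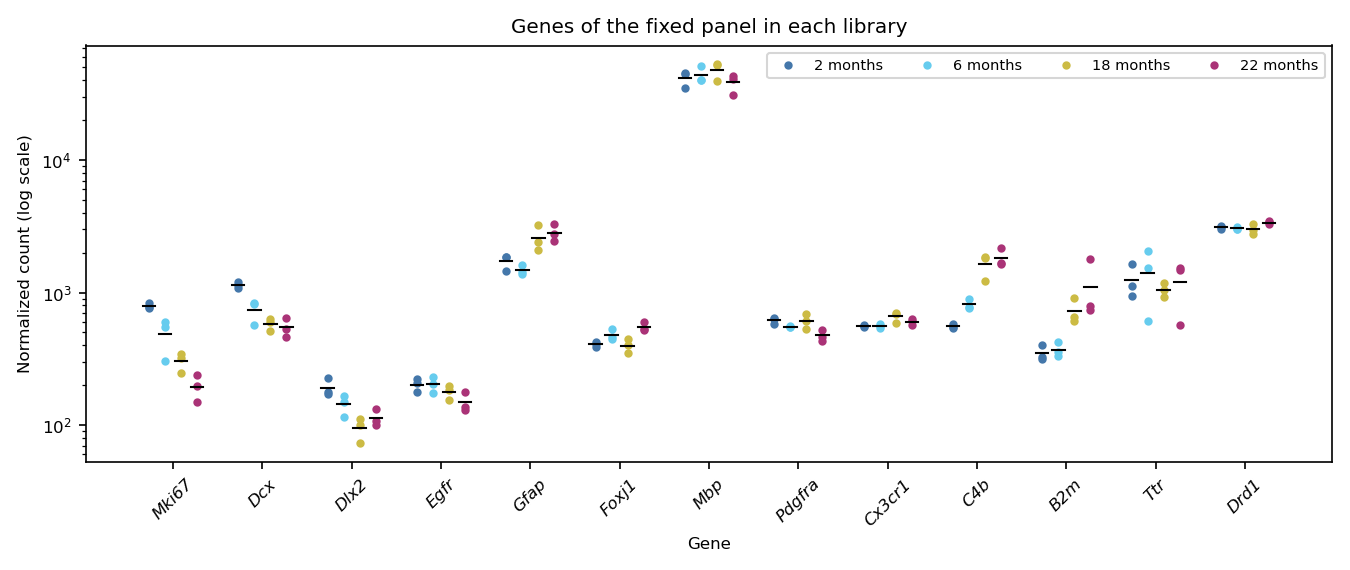
Normalised counts (log scale) of 13 of the 16 panel genes in each library at 2, 6, 18 and 22 months, with points for libraries and bars for means of 3. Mki67 falls from a mean of 793 at 2 months to 194 at 22 months, while C4b goes from 557 to 1832.

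From 2 to 6 months, transcripts of dividing cells, young neurons and cholesterol synthesis fell, and transcripts of complement C3 and globins rose. The changes of lists rest on the preset correlation, as 0 of the 29 tested lists passed with an estimated correlation. Slc4a11 (id269356, chromosome 2, 130684107 to 130697519), a membrane transporter of the bicarbonate transporter family, rose by 1.59 ± 0.11 on the log2 scale (adjusted p = 1.66e-06, limma), from 54.7 to 167 normalised counts. C3 (id12266, chromosome 17, 57203967 to 57228136), the central complement component, rose by 1.77 ± 0.20 (0.000352), from 30.7 to 111. Rpe65, the isomerase of the visual cycle, rose by 1.85 ± 0.21 (0.000352), from 10.1 to 38.5. Plin4, a lipid droplet coat protein, rose by 1.94 ± 0.34, from 130 to 521, and Zbtb16, a zinc finger transcription factor, by 1.54 ± 0.23, from 54.0 to 157. Gpr17 (id574402, chromosome 18, 31942999 to 31949890), a receptor of differentiating oligodendrocyte precursors, fell by 0.54 ± 0.08 (0.00302), from 723 to 496, and Sox11, a transcription factor of young neurons, fell by 0.55 ± 0.09 (0.00877), from 661 to 453. The small GTPase Rnd3 fell by 0.76 ± 0.10 (0.00131), from 492 to 291.

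The other genes that the rule named as higher at 6 months were Grrp1, Xdh (xanthine dehydrogenase), Cyp2a4 (a cytochrome P450 whose reads may be shared with Cyp2a5), Fbxw18 and Hif3a (a subunit of the hypoxia-inducible factors), with log2 fold changes from 1.34 to 1.77. Those named as lower were Cenpf, Top2a, Ncapg and Prc1, which act in mitosis, the matrix glycoprotein Tnc, the fatty acid binding protein Fabp7 of radial glia, Car8, Igfbpl1 and the guidance molecule Sema5a, with log2 fold changes from -0.97 to -0.65. 

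Among the fixed lists, proliferation fell from 2 to 6 months: 4 of its 32 tested members fell (Ccnd2, Top2a, Prc1 and Cenpf), 28 did not pass, and 14 were lower when adjusted over the list alone (median -0.39, camera adjusted p = 1.89e-14, adjusted p = 0.084 with an estimated correlation). Neuroblast markers fell, with 5 of 22 lower, 17 not passing and 9 lower adjusted over the list alone (1.67e-05, adjusted p = 0.0877 with an estimated correlation). Dcx fell by 0.64 ± 0.13, Dlx6as1 by 0.55 ± 0.11 and Cd24a by 0.39 ± 0.09. Markers of activated stem cells and transit-amplifying progenitors fell, with 1 of 15 lower (Fabp7), 14 not passing and 5 lower adjusted over the list alone (0.000159, adjusted p = 0.0918 with an estimated correlation). Cholesterol synthesis fell, with 5 of 20 lower, 15 not passing and 7 lower adjusted over the list alone (0.000215, adjusted p = 0.322 with an estimated correlation). Its member Hmgcs1, an enzyme of the early steps, fell by 0.39 ± 0.05, and Idi1 and Cyp51 fell by 0.41 ± 0.07 and 0.40 ± 0.08. Oligodendrocyte precursor markers fell, with 1 of 12 lower (Gpr17), 11 not passing and 1 adjusted over the list alone (0.025, adjusted p = 0.519 with an estimated correlation). That call ended without 2 months replicate 1 (0.165) or replicate 2 (0.0715).

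The erythroid list rose from 2 to 6 months, with 3 of 6 members higher, 3 not passing and 3 higher adjusted over the list alone (median 0.66, 0.00615, adjusted p = 0.322 with an estimated correlation). Its globin members Hba-a2 and Beta-s, which mark blood in the tissue, rose by 0.91 ± 0.17 and 0.86 ± 0.15. Heat shock proteins and chaperones rose, with 2 of 14 higher (Hspa1a by 0.73 ± 0.15 and Hspa1b by 0.71 ± 0.15), 12 not passing and 4 adjusted over the list alone (0.0165, adjusted p = 0.792 with an estimated correlation). That call ended without 2 months replicate 1 (0.0673) or 6 months replicate 1 (0.248). Cytosolic ribosomal proteins rose, with 1 of 35 higher (Rpl37 by 0.31 ± 0.06), 34 not passing and 6 adjusted over the list alone (median 0.08, 7.02e-05, adjusted p = 0.792 with an estimated correlation). That call ended without 6 months replicate 1 (0.0808) and when the trend over transcript length and GC content was removed (0.12), an alternative chosen after seeing the data. The remaining 21 tested lists did not pass, among them complement (1 of 13 higher, 12 not passing, 5 higher adjusted over the list alone, 0.0709), antigen presentation (0 of 17, 0.0699), ependymal markers (0.0738) and microglia markers (0 of 22 over all genes, 3 higher and 1 lower adjusted over the list alone, 0.247). Ependymal markers passed as lower with that trend removed (0.0331), and antigen presentation and complement passed as higher with the replicate number as a block (0.0174 and 0.0213). Antigen presentation also passed as higher in a fit without the 22-month libraries (0.0118), chosen after seeing the data.

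With limma, 145 of 15663 genes passed at 6 against 2 months, 95 higher and 50 lower, and 2405 had an unadjusted p under 0.05. Ages did not overlap for 22.7% of genes, where chance gives 10%, and 58 of the passing genes changed by at least 1.5-fold. The count was 39 without 2 months replicate 1, 49 without 2 months replicate 2, 47 without 6 months replicate 1, 80 without 6 months replicate 2, 65 without 6 months replicate 3 and 266 without 22 months replicate 1, and DESeq2 gave 238 (153 higher and 85 lower). It was 17 without an intensity trend and 92 without a filter on low values. Of 40 named calls, 8 passed without each library in turn (C3, Gpr17, Hmgcs1, Rnd3, Rpe65, Slc4a11, Sox11 and Zbtb16), and the other 32 were lost without at least 1 library. Of the 40, 10 were lost with the length and GC trend removed and 15 with DESeq2. Across 14853 genes, Spearman's rho of fold change at 6 against 2 months was 0.415 with GC content and -0.204 with transcript length.

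From 6 to 18 months, microglial and complement transcripts rose and cell cycle transcripts fell further. The proliferation, activated stem cell, activated microglia and complement lists also passed with an estimated correlation. The other called lists, microglia markers among them (camera adjusted p = 0.0736), passed with the preset correlation alone. Of the 10 ways to split the libraries of these ages into groups of equal size, 2 called at least 13 lists, the real one included. The highest other split called 18 lists. Clec7a (id56644, chromosome 6, 129461591 to 129472785), a pattern recognition receptor of activated microglia, rose by 2.03 ± 0.29 on the log2 scale (adjusted p = 0.00519, limma), from 7.0 to 30.5 normalised counts. Lyz2 (id17105, chromosome 10, 117277541 to 117282272), the lysozyme of myeloid cells, rose by 1.14 ± 0.14 (0.0019), from 66.1 to 145, and its neighbour Lyz1, with which it may share reads, by 1.09 ± 0.13. C4b (id12268, chromosome 17, 34728139 to 34743902) rose by 0.99 ± 0.13 (0.00228), from 813 to 1640, as did the similar C4a by 1.00 ± 0.13. Ccnd2 (id12444, chromosome 6, 127125162 to 127152188), a cyclin of the G1 phase, fell by 0.62 ± 0.08 (0.0019), from 1301 to 842, and Zmym1, a zinc finger protein, fell by 0.76 ± 0.11 (0.00443), from 393 to 231.

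The other genes named as higher at 18 months were Zc3hav1, an antiviral RNA-binding protein, at 1.14 ± 0.19, Gfap at 0.78 ± 0.13, Bmp7, a secreted BMP ligand, at 0.74 ± 0.14, Ctss, a lysosomal protease of microglia, at 0.58 ± 0.10, and Cirbp, a cold-inducible RNA-binding protein, at 0.36 ± 0.07. Lower were Mex3a, an RNA-binding protein, at -0.88 ± 0.15, Dok3 at -0.78 ± 0.14, the chromatin protein Hmgb2 at -0.60 ± 0.10, the nuclear lamin Lmnb1 at -0.57 ± 0.10, Gpr17 at -0.44 ± 0.08, Rhbdl3 at -0.43 ± 0.08, and Marcksl1 at -0.42 ± 0.08 with its pseudogene copy Marcksl1-ps4 at -0.45 ± 0.08.

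Among the lists, proliferation fell from 6 to 18 months, with 2 of 32 members lower (Ccnd2 and Hmgb2), 30 not passing and 17 lower adjusted over the list alone (median -0.46, camera adjusted p = 9.89e-20, 0.0328 with an estimated correlation). Activated stem cell and progenitor markers fell, with 0 of 15 passing over all genes and 1 higher and 7 lower adjusted over the list alone (median -0.26, 1.63e-06, 0.039 with an estimated correlation). Mycn, a transcription factor of growth, had -0.53 ± 0.14 (adjusted p = 0.184). Activated microglia genes rose, with 2 of 18 higher (Lyz2 and Clec7a), 16 not passing and 9 higher adjusted over the list alone (median 0.45, 5.66e-13, 0.039 with an estimated correlation). Complement rose, with 1 of 13 higher (C4b), 12 not passing and 7 higher adjusted over the list alone (median 0.38, 2.58e-08, 0.039 with an estimated correlation). Microglia markers rose, with 1 of 22 higher (Ctss), 21 not passing and 14 higher adjusted over the list alone (median 0.27, 4.33e-13, adjusted p = 0.0736 with an estimated correlation).

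Interferon-stimulated genes rose as a list from 6 to 18 months, with 0 of 24 passing over all genes and 11 higher adjusted over the list alone (median 0.89, 8.35e-10, adjusted p = 0.356 with an estimated correlation). Trim30a had 1.17 ± 0.28 (0.144) and Bst2 1.5 ± 0.43 (0.22). Antigen presentation rose, with 0 of 17 passing and 8 higher adjusted over the list alone (median 0.70, 1.37e-06, adjusted p = 0.327 with an estimated correlation). B2m had 0.95 ± 0.24 (0.157). Neuroblast markers fell, with 0 of 22 passing and 5 lower adjusted over the list alone (median -0.11, 0.000137, adjusted p = 0.0736 with an estimated correlation). Heat shock proteins fell, with 1 of 14 lower (Hsph1 at -0.29 ± 0.05), 13 not passing and 9 lower adjusted over the list alone (median -0.18, 1.18e-08, adjusted p = 0.131 with an estimated correlation).

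4 more lists passed at 18 against 6 months with 0 members passing over all genes or adjusted over the list alone. Oligodendrocyte markers rose (20 tested, median 0.14, 0.00434, adjusted p = 0.821 with an estimated correlation). That call ended without 6 months replicate 2 (0.144), 6 months replicate 3 (0.0691), 18 months replicate 2 (0.123) or 18 months replicate 3 (0.259). Striatal projection neuron markers fell (20 tested, median -0.07, 0.00715, adjusted p = 0.404 with an estimated correlation). The call ended without 18 months replicate 1 (0.12) or replicate 3 (0.0669). Immediate early genes, which respond within minutes to neuronal activity or handling, fell (22 tested, median -0.37, 0.018, adjusted p = 0.821 with an estimated correlation). That call ended without 6 months replicate 2 (0.118), 6 months replicate 3 (0.0776) or 18 months replicate 1 (0.578), and with the length and GC trend removed (0.107). Hedgehog and Notch signalling fell (27 tested, median -0.08, 0.018, adjusted p = 0.204 with an estimated correlation). The call ended without 6 months replicate 3 (0.0776) or 18 months replicate 2 (0.196), and with that trend removed (0.124).

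With limma, 24 of 15663 genes passed at 18 against 6 months, 11 higher and 13 lower, and 1440 had an unadjusted p under 0.05. Ages did not overlap for 16.2% of genes, where chance gives 10%. DESeq2 gave 63 (26 higher and 37 lower), edgeR, chosen after seeing the data, gave 38 (22 higher and 16 lower), and a fit without the 22-month libraries, also chosen after seeing the data, gave 40. Without an intensity trend 3 passed, and without a filter on low values 13. The count was 45 without 6 months replicate 1, 8 without 6 months replicate 2, 14 without 18 months replicate 1, 13 without 18 months replicate 2, 8 without 18 months replicate 3 and 67 without 22 months replicate 1. Of 23 named calls, 7 passed without each library in turn (C4a, C4b, Ccnd2, Clec7a, Lyz1, Lyz2 and Zmym1), and the other 16 were lost without at least 1 library.

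From 18 to 22 months, myelin transcripts fell, and transcripts of astrocytes, ependymal cells, striatal neurons, ribosomes and the respiratory chain rose. All of these are list results at the preset correlation, and 0 of 29 lists passed with an estimated correlation (adjusted p = 0.475 for each of the 6). Gjc3 (a connexin of oligodendrocytes) and Myrf (the transcription factor of myelination) fell by 0.65 ± 0.09 and 0.70 ± 0.13 on the log2 scale. Grin2b (id14812, chromosome 6, 135713221 to 136173615), an NMDA receptor subunit with a transcript of 24060 nt, fell by 1.95 ± 0.35 (adjusted p = 0.00153, limma), from 577 to 140. Adora2a, the adenosine receptor of striatal projection neurons, rose by 0.40 ± 0.06 (0.000386), from 3071 to 4047, and Apoe, a lipid carrier of astrocytes, rose by 0.33 ± 0.06 (0.00145), from 13780 to 17280. Ide (id15925, chromosome 19, 37268743 to 37334544), a protease that degrades insulin, rose by 0.99 ± 0.19 (0.00254), from 376 to 749.

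The rule also named as higher at 22 months Prss56, a serine protease (0.97 ± 0.23), Dll4, a Notch ligand (0.96 ± 0.23), Gja5, a connexin of arterial endothelium (1.03 ± 0.32), Ptgr1, a prostaglandin reductase (1.17 ± 0.30), Tmem106a (1.21 ± 0.33), Ang6 (1.03 ± 0.30), Khdc3 (1.65 ± 0.51) and Sprr1a (1.93 ± 0.66). Khdc3 and Sprr1a averaged 7.22 and 3.32 normalised counts at 18 months, near the limit of detection. BB014433 had no read in any 18-month library, which allows up to 2.55, 2.43 and 2.15 normalised counts in the 3 libraries, and averaged 8.78 ± 6.83 at 22 months. Named as lower were the potassium channel Kcng3 (-2.14 ± 0.43), the zinc finger gene Zbtb20 (transcript 26901 nt, -1.86 ± 0.47), the kinase gene Dgkk (-1.83 ± 0.42) and Tmem239 (-2.10 ± 0.59, and -1.24 without 22 months replicate 1, when it no longer passed). Pde11a, Zan and Glra3 also passed and averaged 8.71, 10 and 7.79 at 18 months and 0.691, 1.38 and 1.27 at 22 months, under the limit of 3 reads. Slc17a7, the vesicular glutamate transporter of cortical neurons, had a log2 fold change of -2.13 ± 0.72 (0.0482). It had 453 normalised counts in 18 months replicate 1 against 38.9 and 33.0 in replicates 2 and 3, and without replicate 1 the fold change was -0.93 and did not pass.

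Oligodendrocyte and myelin markers fell from 18 to 22 months, with 15 of 20 lower, 5 not passing and 19 lower adjusted over the list alone (median -0.46, camera adjusted p = 2.78e-08, adjusted p = 0.475 with an estimated correlation). Oligodendrocyte precursor markers fell, with 1 of 12 higher, 5 lower, 6 not passing and the same numbers adjusted over the list alone (median -0.31, 0.00704, adjusted p = 0.475 with an estimated correlation). Gpr17 fell by 0.45 ± 0.08, the matrix glycoprotein Tnr by 0.88 ± 0.16 and the growth factor receptor Pdgfra by 0.35 ± 0.09. With the length and GC trend removed, 2 precursor markers were lower and 0 higher, with a median of -0.16. Quiescent stem cell and astrocyte markers rose, with 8 of 21 higher, 13 not passing, and 10 higher and 1 lower adjusted over the list alone (median 0.17, 0.00519, adjusted p = 0.475 with an estimated correlation). Apoe stood beside Clu (0.29 ± 0.05), a secreted chaperone, and Vcam1 (0.51 ± 0.11), an adhesion molecule of stem cells. Ependymal and cilium markers rose, with 8 of 22 higher, 14 not passing, and 9 higher and 1 lower adjusted over the list alone (median 0.28, 0.00561, adjusted p = 0.475 with an estimated correlation). Foxj1, the regulator of motile cilia, rose by 0.48 ± 0.09 and Rarres2 by 0.44 ± 0.08. With that trend removed, 3 of the 22 were higher. Striatal projection neuron markers, which mark tissue beside the niche, rose with 11 of 20 higher, 9 not passing and 14 higher adjusted over the list alone (median 0.20, 0.000586, adjusted p = 0.475 with an estimated correlation). Gng7 rose by 0.29 ± 0.05 and Pde1b by 0.23 ± 0.05.

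Cytosolic ribosomal proteins rose from 18 to 22 months, with 28 of 35 higher, 7 not passing and 33 higher adjusted over the list alone (median 0.27, 9.86e-13, adjusted p = 0.475 with an estimated correlation). Rplp1 rose by 0.44 ± 0.06 and Rpl37 by 0.36 ± 0.06. Respiratory chain subunits rose, with 19 of 32 higher, 13 not passing and 28 higher adjusted over the list alone (median 0.25, 3.65e-09, adjusted p = 0.475 with an estimated correlation). Sdhb rose by 0.36 ± 0.06, Ndufa1 by 0.52 ± 0.09 and Uqcrb by 0.47 ± 0.09. Both lists hold short transcripts, and with the length and GC trend removed, 6 ribosomal and 7 respiratory members were higher, with medians of 0.11 and 0.13 (camera 5.52e-05 and 0.000743). Heat shock proteins rose, with 4 of 14 higher, 10 not passing and 7 adjusted over the list alone (median 0.17, 0.00561, adjusted p = 0.475 with an estimated correlation). Hspa8 rose by 0.40 ± 0.07 and Hsph1 by 0.30 ± 0.05.

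Each of the other 4 lists that passed at 22 against 18 months was no longer called without at least 1 library. Activated microglia genes rose, with 5 of 18 higher, 13 not passing and 6 adjusted over the list alone (median 0.20, 0.0466, adjusted p = 0.519 with an estimated correlation). The call ended without 2 months replicate 3 (0.0554), 18 months replicate 1 (0.0677), 18 months replicate 2 (0.0957) or 22 months replicate 1 (0.234), and with the length and GC trend removed (0.146). Antigen presentation rose, with 5 of 17 higher, 12 not passing and 5 adjusted over the list alone (median 0.47, 0.0466, adjusted p = 0.618 with an estimated correlation). H2-D1 and H2-Q7, MHC class I genes, rose by 0.70 ± 0.22 and 0.74 ± 0.23. Without 22 months replicate 1 they had 0.38 and 0.40 and did not pass, nor did they pass without 18 months replicate 2 or 3. The list's call ended without 2 months replicate 3 (0.0554), 6 months replicate 1 (0.0615), 6 months replicate 2 (0.0504), 18 months replicate 2 (0.369), 18 months replicate 3 (0.053) or 22 months replicate 1 (0.457), and with the trend removed (0.146). Interferon-stimulated genes rose, with 1 of 24 higher (Ifitm3), 23 not passing and 1 adjusted over the list alone (median 0.61, 0.0487, adjusted p = 0.70 with an estimated correlation), but without 22 months replicate 1 the median was -0.07 (0.335). That call also ended without 2 months replicate 3 (0.0554), 6 months replicates 1, 2 or 3 (0.0638, 0.051 and 0.0521), 18 months replicate 2 (0.38) or replicate 3 (0.0588), and with the trend removed (0.103). Immediate early genes rose, with 1 of 22 higher (Ier2), 21 not passing and 0 adjusted over the list alone (median 0.61, 0.0151, adjusted p = 0.618 with an estimated correlation). That call ended without 18 months replicate 1 (0.173), 22 months replicate 2 (0.172) or 22 months replicate 3 (0.106).

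The remaining 17 tested lists did not pass at 22 against 18 months, among them proliferation (2 of 32 higher and 2 lower, 28 not passing, the same adjusted over the list alone, 0.933), activated stem cells (3 of 15 higher and 1 lower, the same adjusted over the list alone, 0.121) and neuroblasts (4 of 22 higher and 1 lower, 9 higher and 3 lower adjusted over the list alone, 0.213). Mki67 and Cenpe fell by 0.66 ± 0.20 and 0.81 ± 0.17, while Mcm5 and Tpx2 rose by 0.48 ± 0.13 and 0.56 ± 0.17. With the length and GC trend removed, 3 of the 32 proliferation members were higher and 1 was lower. Cd24a rose by 0.49 ± 0.09. Pan-neuronal genes (2 of 20 higher and 4 lower, 0.896) had a median of 0.06 and a mean of -0.18. With the length and GC trend removed, 4 of these 17 lists passed as higher, namely neuroblasts (0.0477), WNT signalling (0.0139), BMP and TGF-beta signalling (0.0237) and Hedgehog and Notch signalling (0.0414). With the replicate number as a block, WNT signalling passed as higher (0.0392) and extracellular matrix as lower (0.0434).

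6 genes of 2 families at 1 place on chromosome 17 (6256726 to 6655965), which were chosen after their values were seen, rose together from 18 to 22 months. They encode membrane proteins of the Tmem181 family and dynein light chains of the Dynlt1 family. Tmem181a rose by 0.79 ± 0.06 (adjusted p = 4.53e-07, limma), Dynlt1a by 0.86 ± 0.06 (7.91e-07), Dynlt1b by 0.48 ± 0.09 (0.00145) and Dynlt1f by 0.72 ± 0.06 (5.64e-06). The pseudogene copies Tmem181b-ps and Tmem181c-ps rose by 0.79 ± 0.06 and 0.87 ± 0.05. The members of each family are similar in sequence and may share reads. Among the 10 nearest tested genes outside, the highest log2 fold change was 0.32 and the lowest was -0.85.

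**Figure D2:**
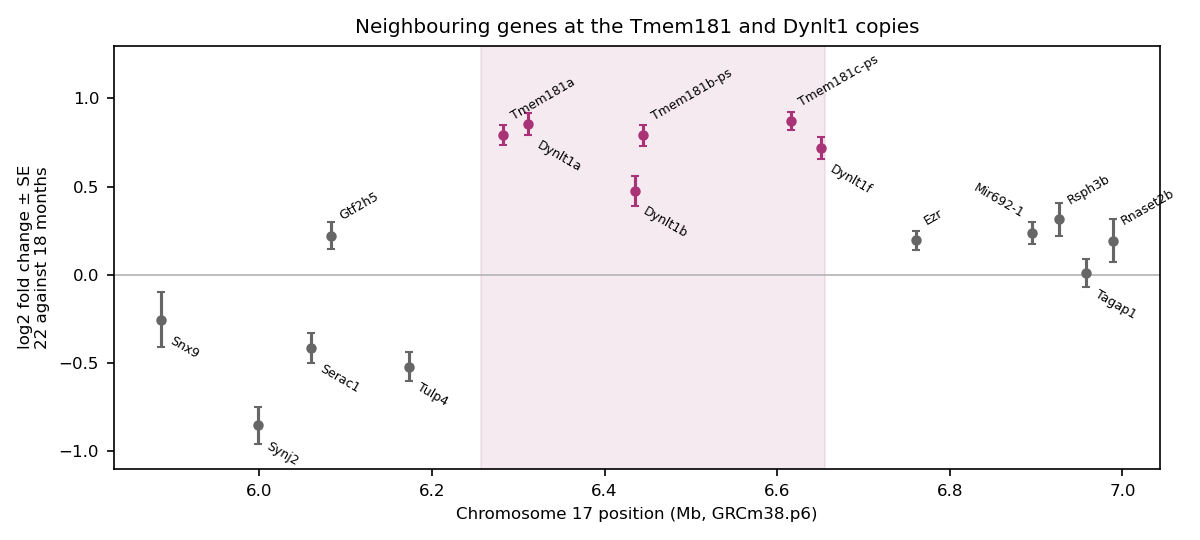
Log2 fold change ± SE at 22 against 18 months (3 against 3 libraries) of the tested genes along chromosome 17, with the interval of the Tmem181 and Dynlt1 genes shaded. The 6 genes inside lie between 0.48 and 0.87, and the highest of the 10 nearest outside lies at 0.32.

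**Figure D3:**
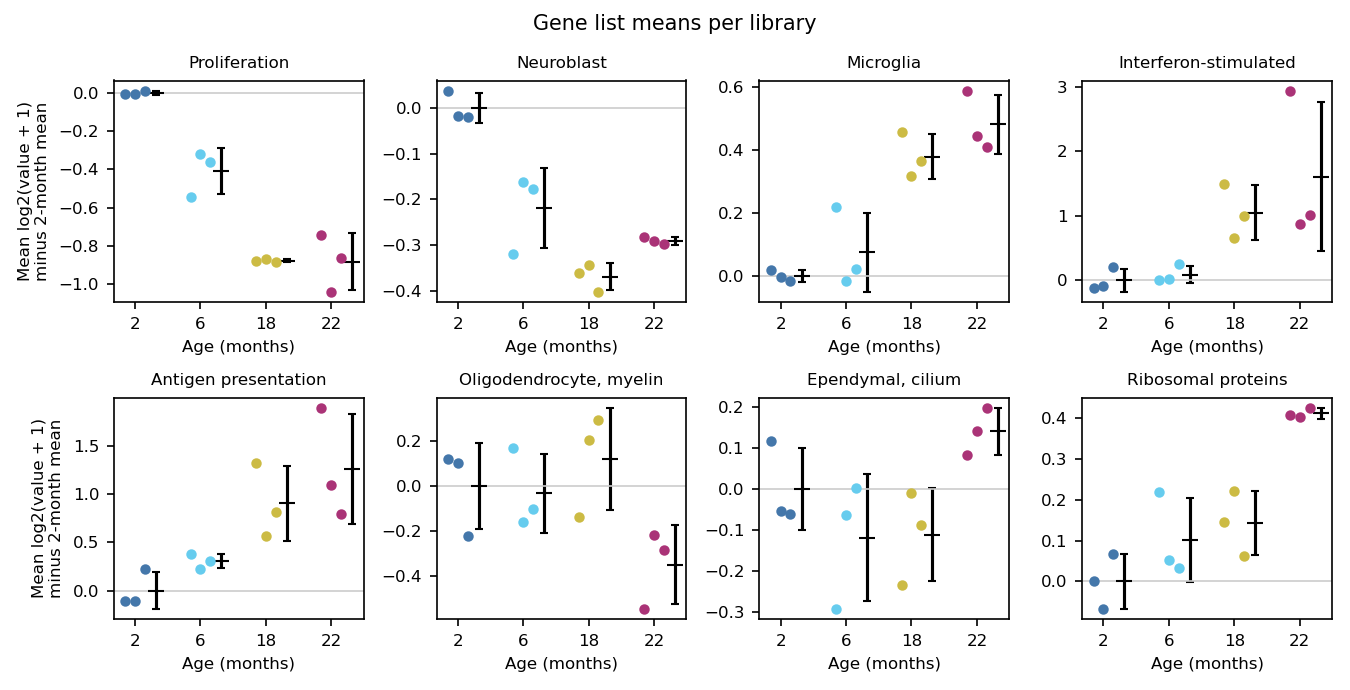
Mean log2 level of 8 gene lists in each library at 2, 6, 18 and 22 months, minus the 2-month mean, with points for libraries and black marks for the mean ± SD of 3. Proliferation lies lower at the 3 later ages, and the interferon list is highest in 22 months replicate 1.

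With limma, 2956 of 15663 genes passed at 22 against 18 months, 1352 higher and 1604 lower, and 5231 had an unadjusted p under 0.05. Ages did not overlap for 34.7% of genes, where chance gives 10%, and 499 passing genes changed by at least 1.5-fold (86 higher and 413 lower). Among the genes with the shortest transcripts (66 to 1997 nt) 18.7% were higher and 1.38% lower, and among those with the longest (5316 to 123179 nt) 1.11% were higher and 35.4% lower. With the trend over length and GC content removed, an alternative chosen after seeing the data, 1574 genes passed, of which 883 were higher and 691 lower, so the direction of the balance turned. The count was 1909 without 18 months replicate 1, 1184 without 18 months replicate 3, 1965 without 22 months replicate 2, 1853 without 22 months replicate 3 and 1840 without an intensity trend. Of 114 named calls, 58 passed without each library in turn, 56 were lost without at least 1, and 46 were lost with the trend removed.

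**Figure D4:**
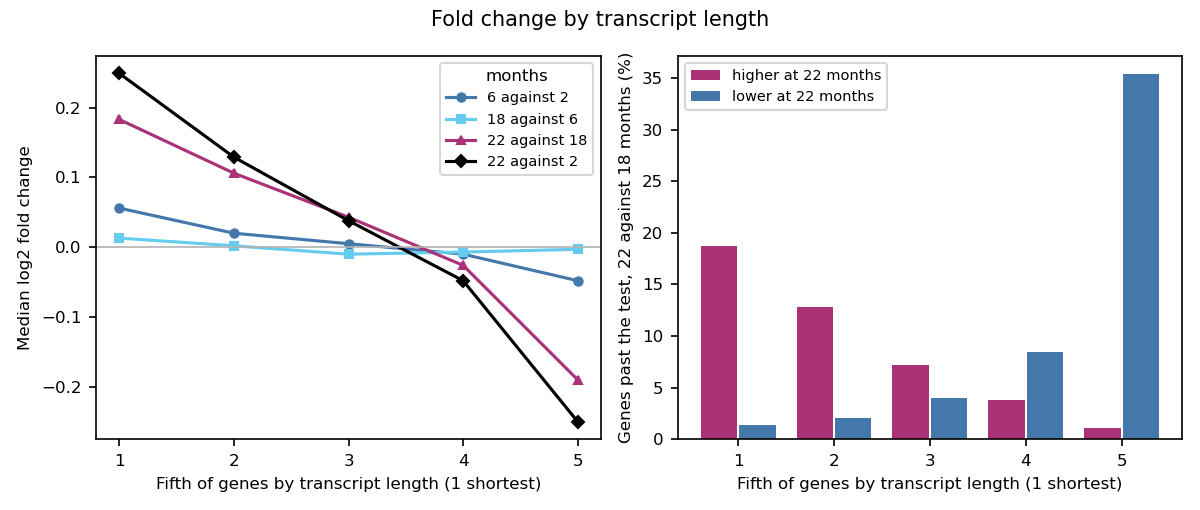
Median log2 fold change for 5 equal groups of genes ordered by transcript length (left, 4 comparisons) and the percentage of genes higher or lower at 22 against 18 months in each group (right). At 22 against 18 months the median goes from 0.18 for the shortest transcripts to -0.19 for the longest.

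From 2 to 22 months, the whole span of ages, cell cycle and progenitor transcripts fell, and transcripts of the complement system, interferon response and antigen presentation rose. With an estimated correlation 0 of 29 lists passed, and the adjusted p of these 5 lists ran from 0.0923 to 0.374. C3 rose by 3.44 ± 0.20 on the log2 scale (adjusted p = 2.53e-08, limma), from 30.7 to 351 normalised counts, and C4b by 1.70 ± 0.13 (4.17e-07), from 557 to 1832. Oasl2 (id23962, chromosome 5, 114896926 to 114912245), an interferon-induced gene, rose by 2.97 ± 0.59 (0.00119), from 24.8 to 349, and by 1.92 without 22 months replicate 1. Top2a, the topoisomerase of dividing cells, fell by 1.76 ± 0.14 (7.02e-07), from 384 to 115, Mki67 fell by 2.05 ± 0.20 (3.78e-06), and Gpr17 fell by 1.43 ± 0.08 (1.15e-08), from 723 to 269.

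The rule also named as higher at 22 months Slc22a18, an organic cation transporter (1.80 ± 3.11 to 19.4 ± 8.16 normalised counts, SD, n = 3), Cyp2a5 (4.89 to 32.1) and 6 vomeronasal receptor genes of 1 cluster on chromosome 13, Vmn1r189, Vmn1r203, Vmn1r206, Vmn1r209, Vmn1r207-ps and Vmn1r221. The vomeronasal genes had means of 0.719 to 1.69 at 2 months, under the limit of 3 reads, and of 10.9 to 17.3 at 22 months. They are similar in sequence and may share reads. Named as lower were Trip13, a checkpoint ATPase (14.8 to 2.34), Rassf10 (21.5 to 5.55), Ngb, which encodes neuroglobin (23.1 to 3.92), Dgkk (34.3 to 5.71), Calcr, the calcitonin receptor (18.9 to 1.61), Myoc (12.3 to 1.18), Arhgap36 (20.1 to 0.924), Pde11a (15.7 to 0.691), Zan (14.9 to 1.38) and Glra3 (11.3 to 1.27). Rassf10 fell by 2.35 ± 0.64, and without 22 months replicate 2 its log2 fold change was -1.29. 

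Proliferation fell from 2 to 22 months, with 25 of 32 lower, 7 not passing and 25 adjusted over the list alone (median -0.78, camera adjusted p = 2.75e-14, adjusted p = 0.0923 with an estimated correlation). Activated stem cell and progenitor markers fell, with 8 of 15 lower, 7 not passing and 9 adjusted over the list alone (median -0.46, 0.000632, adjusted p = 0.233 with an estimated correlation). Dlx1 fell by 0.55 ± 0.11, Dlx2 by 0.75 ± 0.17 and Rrm2, a ribonucleotide reductase subunit, by 1.15 ± 0.24. Neuroblast markers fell, with 4 of 22 higher, 12 lower, 6 not passing and the same numbers adjusted over the list alone (median -0.29, 0.00658, adjusted p = 0.259 with an estimated correlation). Sox11 and Dcx fell by 0.87 ± 0.09 and 1.07 ± 0.13. Oligodendrocyte markers fell, with 9 of 20 lower, 11 not passing and 11 adjusted over the list alone (median -0.32, 0.000744, adjusted p = 0.482 with an estimated correlation). Oligodendrocyte precursor markers fell, with 7 of 12 lower, 5 not passing and 7 adjusted over the list alone (median -0.33, 0.00214, adjusted p = 0.265 with an estimated correlation). Extracellular matrix fell, with 2 of 27 higher (Sparc among them, by 0.54 ± 0.08), 9 lower (Tnc by 1.61 ± 0.18), 16 not passing and the same adjusted over the list alone (median -0.21, 0.0111, adjusted p = 0.374 with an estimated correlation). That call ended with the length and GC trend removed (0.215). Cholesterol synthesis fell, with 7 of 20 lower, 13 not passing and 7 adjusted over the list alone (median -0.03, 0.0329, adjusted p = 0.374 with an estimated correlation). The call ended without 2 months replicate 1 (0.0521) or 22 months replicate 1 (0.0894). Hmgcs1 and Idi1 fell by 0.65 ± 0.05 and 0.68 ± 0.07.

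Interferon-stimulated genes rose from 2 to 22 months, with 20 of 24 higher, 4 not passing and 21 adjusted over the list alone (median 1.61, 2.67e-06, adjusted p = 0.374 with an estimated correlation). Without 22 months replicate 1, 14 of the 24 were higher and their median was 0.92. Bst2, an antiviral membrane protein, rose by 2.59 ± 0.43 and Ifitm3 by 1.5 ± 0.21. Antigen presentation rose, with 13 of 17 higher, 4 not passing and 13 adjusted over the list alone (median 1.65, 1.41e-05, adjusted p = 0.326 with an estimated correlation). Its member B2m had 1790 normalised counts in 22 months replicate 1 against 736 and 796.5 in replicates 2 and 3, and 315.5 to 399.8 at 2 months. The class I genes H2-Q4 and H2-D1 rose by 1.82 ± 0.23 and 1.72 ± 0.22. Microglia markers rose, with 13 of 22 higher, 1 lower, 8 not passing and the same adjusted over the list alone (median 0.44, 2.97e-05, adjusted p = 0.294 with an estimated correlation). C1qb and Ctss rose by 1.06 ± 0.08 and 1.07 ± 0.10. Activated microglia genes rose, with 13 of 18 higher, 5 not passing and 14 adjusted over the list alone (median 0.61, 2.26e-06, adjusted p = 0.233 with an estimated correlation). Itgax rose by 2.07 ± 0.30. Complement rose, with 6 of 13 higher, 7 not passing and 7 adjusted over the list alone (median 0.62, 0.000214, adjusted p = 0.233 with an estimated correlation).

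Quiescent stem cell and astrocyte markers rose from 2 to 22 months, with 15 of 21 higher, 3 lower, 3 not passing and the same adjusted over the list alone (median 0.27, 0.0042, adjusted p = 0.259 with an estimated correlation). Apoe rose by 0.75 ± 0.06 and Aldoc, a glycolytic enzyme of astrocytes, by 0.43 ± 0.06, and Thbs4 fell by 0.84 ± 0.10. Ribosomal proteins rose, with 33 of 35 higher, 2 not passing and 34 adjusted over the list alone (median 0.40, 1.11e-14, adjusted p = 0.265 with an estimated correlation). Respiratory chain subunits rose, with 29 of 32 higher, 3 not passing and 31 adjusted over the list alone (median 0.35, 3.27e-10, adjusted p = 0.294 with an estimated correlation). With the length and GC trend removed, 17 ribosomal and 12 respiratory members were higher, and among quiescent stem cell and astrocyte markers 9 were higher and 1 lower. Striatal projection neuron markers rose, with 10 of 20 higher, 1 lower, 9 not passing and the same adjusted over the list alone (median 0.13, 0.0179, adjusted p = 0.374 with an estimated correlation). The precursor of substance P, Tac1, rose by 0.60 ± 0.09. Endothelial markers rose, with 6 of 20 higher, 14 not passing and 6 adjusted over the list alone (median 0.22, 0.0329, adjusted p = 0.374 with an estimated correlation). The call ended without 2 months replicate 1 (0.158) or 22 months replicate 2 (0.0592). The erythroid list rose, with 4 of 6 higher (3 of them globin genes), 2 not passing and 4 adjusted over the list alone (median 0.70, 0.0111, adjusted p = 0.265 with an estimated correlation).

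The other lists did not pass at 22 against 2 months, although with the length and GC trend removed WNT signalling (0.0174) and BMP and TGF-beta signalling (0.00587) passed as higher, and WNT signalling did with the replicate number as a block (0.0494). Ependymal markers had 6 of 22 higher and 1 lower (0.207), pericyte, smooth muscle and fibroblast markers 4 of 15 higher and 2 lower (0.959), choroid plexus markers 2 of 15 higher and 1 lower (0.779) and pan-neuronal genes 8 of 20 higher and 3 lower (0.24, median 0.08, mean -0.08). Immediate early genes had 3 of 22 higher (0.396), heat shock proteins 2 of 14 higher and 1 lower (0.207), and senescence genes 2 of 12 higher and 3 lower (0.779), with Lmnb1 lower by 0.73 ± 0.10 in limma. WNT signalling had 7 of 26 higher and 1 lower (0.0702), with Dkk3 higher by 0.56 ± 0.06. BMP and TGF-beta signalling had 10 of 29 higher and 4 lower (0.189), with Bmp7 higher by 1.3 ± 0.14. Hedgehog and Notch signalling had 7 of 27 higher and 4 lower (0.959) and secreted growth factors 6 of 24 higher and 0 lower (0.351). Adjusted over the list alone, these 11 lists had 6 and 1, 4 and 2, 0 and 1, 9 and 4, 2 and 0, 2 and 1, 2 and 3, 5 and 1, 11 and 5, 7 and 4, and 3 and 0 members higher and lower in the same order. T and B lymphocyte markers had 3 tested members, too few for the test, and 0 passed by limma in any comparison.

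With limma, 5584 of 15663 genes passed at 22 against 2 months, 2889 higher and 2695 lower, and 7067 had an unadjusted p under 0.05. Ages did not overlap for 46.4% of genes, where chance gives 10%, and 1364 passing genes changed by at least 1.5-fold. With the length and GC trend removed, 3314 passed. Of 131 named calls, 119 passed without each library in turn, 12 were lost without at least 1, and 27 were lost with that trend removed.

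At 18 against 2 months, with all 12 libraries in the fit, 1141 genes passed with limma, 617 higher and 524 lower, and 1210 passed in a fit without the 22-month libraries, chosen after seeing the data. Ages did not overlap for 27.6% of genes (chance gives 10%). Ccnd2 fell by 1.07 ± 0.08 (adjusted p = 8.28e-07), Sox11 by 0.98 ± 0.09 (7.95e-06) and Igfbpl1 by 1.28 ± 0.15 (8.42e-05), and C3 rose by 2.69 ± 0.20 (8.28e-07). Proliferation had 23 of 32 members lower (27 adjusted over the list alone), activated stem cells 9 of 15 lower (1 higher and 11 lower adjusted over the list alone) and neuroblasts 10 of 22 lower (12 adjusted over the list alone). These 3 lists held with an estimated correlation (camera adjusted p = 0.0112, 0.0147 and 0.0194), and the other 9 of the 12 lists called with the preset correlation did not (adjusted p = 0.0733 to 0.641). Of these 9, cholesterol synthesis fell (0.00138), and microglia markers (1.86e-08), activated microglia genes (3.09e-07), interferon-stimulated genes (1.08e-06), antigen presentation (7.07e-07), complement (8.58e-07), ribosomal proteins (7.07e-07), respiratory chain subunits (0.00402) and erythroid genes (0.0117) rose. The respiratory call ended without 2 months replicate 2 (0.0615) or 18 months replicate 2 (0.2) and with the length and GC trend removed (0.276), and the erythroid call without 18 months replicate 1 (0.065). Oligodendrocyte precursor markers (0.0547) passed as lower with that trend removed (0.0485). Immediate early genes (0.119) passed as lower with the replicate number as a block (0.00139). The count was 633, 628 and 726 without 2 months replicates 1, 2 and 3, and 707, 755 and 592 without 18 months replicates 1, 2 and 3. It was 700 without an intensity trend.

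At 22 against 6 months, 3480 genes passed with limma, 1659 higher and 1821 lower, and ages did not overlap for 37.2% of genes (chance gives 10%). Clec7a rose by 2.75 ± 0.29 (adjusted p = 3.67e-05), Lyz2 by 1.61 ± 0.14 (3.85e-06) and Gfap by 0.93 ± 0.13 (0.000305), and Gpr17 fell by 0.89 ± 0.08 (2.68e-06) and Gjc3 by 0.50 ± 0.09 (0.00104). 14 lists passed with the preset correlation and 0 with an estimated one (adjusted p = 0.174 to 0.498 for the 14). Lower were proliferation (12 of 32 members, 17 adjusted over the list alone, 5.72e-08), myelin (9 of 20, 13, 0.000111), oligodendrocyte precursors (4 of 12, 4, 0.00671) and extracellular matrix (8 of 27, with 2 higher, 9 and 2, 0.0188). Higher were ribosomal proteins (34 of 35 members, 34 adjusted over the list alone, 2.11e-14), respiratory chain subunits (26 of 32, 29, 6.86e-11), microglia markers (14 of 22, 14, 1.26e-06), activated microglia genes (12 of 18, 15, 3.26e-08) and interferon-stimulated genes (16 of 24, 20, 1.45e-07). So were antigen presentation (12 of 17, 12 and 1 lower, 1.86e-05), complement (6 of 13, 6, 4.73e-05), quiescent stem cell and astrocyte markers (10 of 21 with 1 lower, 13 and 1, 0.000505), ependymal markers (6 of 22, 6, 0.00581) and striatal markers (7 of 20, 7, 0.0454). Without 6 months replicate 1 the ependymal (0.168), striatal (0.167) and matrix (0.0536) calls ended, as did the striatal call without 22 months replicate 2 (0.145). The matrix call also ended with the length and GC trend removed (0.874), when WNT (0.0426) and BMP and TGF-beta signalling (0.00115) passed as higher. The count was 1790 without 6 months replicate 2 and 1925 without 6 months replicate 3, and 1871 with the length and GC trend removed.

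**Figure D5:**
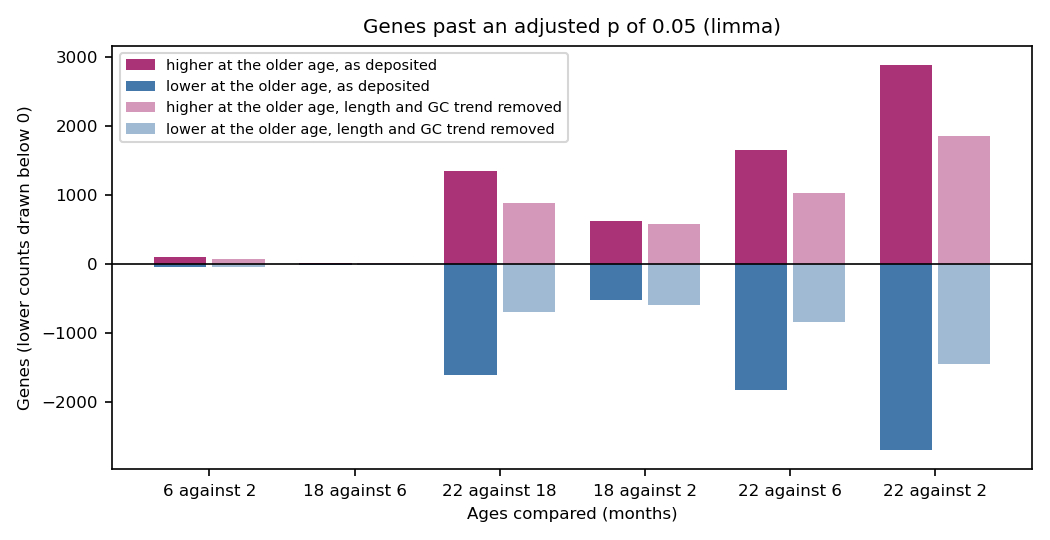
Genes higher (above 0) and lower (below 0) in each comparison of ages with limma, as measured and with the trend over transcript length and GC content removed. At 22 against 18 months the bars go from 1352 higher and 1604 lower to 883 higher and 691 lower.

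5 genes turned at 18 months, all lower at 18 than at 6 and higher at 22 than at 18 months, and 0 turned the other way. Mex3a (id72640, chromosome 3, 88531946 to 88541394), an RNA-binding protein, had 205 ± 15.5, 161 ± 34.9, 85.8 ± 5.40 and 127 ± 18.3 normalised counts at 2, 6, 18 and 22 months (SD, n = 3). Sbk1 (id104175, chromosome 7), a kinase gene, had 1084 ± 55.0, 1053 ± 20.1, 825 ± 37.0 and 1021 ± 27.3, and Hsph1 (id15505, chromosome 5), a chaperone, had 3149 ± 14.3, 3275 ± 185, 2678 ± 139 and 3289 ± 65.4. Dlx1as (id111970, chromosome 2), an antisense transcript at Dlx1 whose strand could not be told apart from the table, had 448 ± 14.1, 333 ± 25.8, 251 ± 15.2 and 301 ± 11. Marcksl1-ps4 (id111002, chromosome 13), a pseudogene copy that may share reads with Marcksl1, had 491 ± 18.3, 370 ± 19.5, 272 ± 24.4 and 319 ± 16.0. At 22 against 2 months Sbk1 (-0.09, adjusted p = 0.251) and Hsph1 (0.06, 0.375) did not pass, whereas Mex3a (-0.69, 0.00174), Dlx1as (-0.57, 6.59e-05) and Marcksl1-ps4 (-0.62, 4.16e-05) were lower in limma.

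In 100 simulated sets with independent noise and no age effect in any gene, the mean was 0.02 turns and the highest was 1. The simulation leaves out the age differences of other genes and any variation shared by genes of a library. Its counts are therefore not the number expected by chance in these libraries. The count was 8 with DESeq2, 2 without 2 months replicate 1 or 2, 12 without 6 months replicate 1, 0 without 6 months replicate 2, 3 without 6 months replicate 3, 3, 2 and 0 without 18 months replicates 1, 2 and 3, and 14, 3 and 1 without 22 months replicates 1, 2 and 3. It was 0 without an intensity trend, 2 without a filter on low values, 3 with quantile normalisation, 3 with the replicate number as a block and 0 for changes of at least 1.5-fold. At 6 months 0 genes turned with limma, which called 145 and 24 genes in the steps on either side (2405 and 1440 at an unadjusted p under 0.05), against 5 with DESeq2 and 1 with edgeR. It was 1 without 2 months replicate 3, 2 without 6 months replicate 3 and 1 without 22 months replicate 1. Among the lists, heat shock proteins rose at 6, fell at 18 and rose at 22 months with the preset correlation, and striatal neuron markers and immediate early genes fell at 18 and rose at 22 months. None of these calls held with an estimated correlation, with adjusted p-values of 0.792, 0.131 and 0.475 for heat shock proteins, 0.404 and 0.475 for striatal markers and 0.821 and 0.618 for immediate early genes.

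Over all ages together, 4936 of 15663 genes (31.5%) passed the F test of limma, and 1409 of them differed by at least 1.5-fold between some pair of ages. With the length and GC trend removed, 3137 genes passed.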

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

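The alternatives with edgeR, with the length and GC trend removed, with the genes of known transcript length alone, with thinned reads and without the 22-month libraries were chosen after seeing the data. Over 27 settings, 827 log2 fold changes of named genes gave 21767 other values, of which 20040 kept their direction and their side of the threshold, 1437 were no longer called, 282 were newly called and 8 reversed. Of 328 other values of the counts of genes and lists, 252 lay within 1.5 times the reported count and 76 did not. With DESeq2, 238 genes passed at 6 against 2 months and 63 at 18 against 6 months, and 8 genes turned at 18 and 5 at 6 months. Without an intensity trend the counts were 17 at 6 against 2 months, 3 at 18 against 6 months, 1840 at 22 against 18 months and 700 at 18 against 2 months, and 0 genes turned at 18 months. Without a filter they were 92 at 6 against 2 months and 13 at 18 against 6 months, with 2 turns at 18 months. Quantile normalisation, the replicate block and the genes of known transcript length gave 3 turns at 18 months each. The replicate numbers did not pair the samples, since same-number correlations of residuals ran from -0.187 to 0.159. At a fold change of at least 1.5, which by its construction lowers every count, the counts were 58 at 6 against 2 months, 13 at 18 against 6 months, 499 at 22 against 18 months, 1364 at 22 against 2 months, 425 at 18 against 2 months, 687 at 22 against 6 months and 1409 for any age, with 0 turns at 18 months. With edgeR, 38 genes passed at 18 against 6 months and 1 turned at 6 months. With the length and GC trend removed, 1574 passed at 22 against 18 months, 3314 at 22 against 2 months, 1871 at 22 against 6 months and 3137 for any age. Without the 22-month libraries, 40 passed at 18 against 6 months. With an estimated correlation the list tests passed for 0 lists at 6 against 2 months, 4 at 18 against 6 months, 0 at 22 against 18 months, 0 at 22 against 2 months, 3 at 18 against 2 months and 0 at 22 against 6 months. The cause of these differences was not tested, apart from the fold change limit.

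The 8 reversals all came with the length and GC trend removed, and the cause was not tested beyond that removal. They were Bmpr2 (0.193), Dnahc5 (0.018) and Hspa4l (0.248) at 22 against 2 months, Hspa4l (0.084), Notch1 (0.012), Robo2 (0.041) and Trpm3 (0.024) at 22 against 6 months, and Vcan (0.008) at 22 against 18 months. Leaving out each library in turn gave 39 to 266 genes at 6 against 2 months, 8 to 67 at 18 against 6 months, 1184 to 3319 at 22 against 18 months, 592 to 1348 at 18 against 2 months and 1790 to 3886 at 22 against 6 months. It gave 0 to 14 turns at 18 months, 0 to 2 turns at 6 months and 7 to 14 lists at 6 against 2 months. The counts at 22 against 2 months (4172 to 5775) and for any age (3538 to 5306) stayed within 1.5 times the reported count. Genes that reached 10 normalised counts in fewer than 3 of the 12 libraries were not tested, and a count of 0 allows up to 4.41 normalised counts in the smallest library.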

Other observations

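The tests of the age of the mice, of the chromosome 17 and chromosome 19 intervals, of the interferon genes, and the closer match of the ribosomal and respiratory lists were chosen only after the result was seen, as were the genes of 18 months replicate 1 and the scan of neighbouring genes.

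Single genes of secreted signals and their receptors, and 1 cell cycle inhibitor, differed between 2 and 22 months. Their lists did not pass, apart from the endothelial list, which holds Egfl7 (camera adjusted p = 0.0329, and 0.374 with an estimated correlation). With the length and GC trend removed, WNT (0.0174) and BMP and TGF-beta signalling (0.00587) also passed, as did WNT signalling with the replicate number as a block (0.0494). The WNT ligands Wnt7b and Wnt4 rose by 0.67 ± 0.11 (adjusted p = 0.000227, limma) and 0.95 ± 0.21 (0.00233) on the log2 scale (n = 3 against 3), and Sfrp5, a secreted WNT antagonist, rose by 1.22 ± 0.21 (0.000332). The BMP ligand Bmp6 rose by 0.95 ± 0.17, from 108 to 204 normalised counts, and the TGF-beta receptor gene Tgfbr2 rose by 0.59 ± 0.08. Among growth factors, Vegfb, a ligand of vascular receptors, rose by 0.51 ± 0.08 and the chemokine Cxcl12 by 0.61 ± 0.13. Egfl7, an endothelial secreted protein, rose by 0.52 ± 0.11 and Vtn, which encodes vitronectin, by 0.62 ± 0.09. Hhip, an inhibitor of Hedgehog ligands, fell by 0.76 ± 0.11, and the cell cycle inhibitor Cdkn1b fell by 0.44 ± 0.07.

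18 months replicate 1 stood apart from the other 18-month libraries in a few genes. Ngb had 49.3 normalised counts there against 4.86 and 5.02 in replicates 2 and 3, and Arhgap36 had 44.2 against 1.62 and 5.02. Myoc had 44.2 against 1.62 and 7.89, and Calcr had 19.6 against 2.43 and 5.74. Over all tested genes in order along the chromosomes, 16 of 15573 windows of 4 neighbours had all 4 log2 fold changes past 0.5 in 1 direction at 22 against 18 months. The 2 windows with the largest changes lay on chromosome 5 from Gm5862 to Gm10220 and held Speer4a (all 4 genes lower by at least 1.423). The chromosome 17 interval below was not among the 16. Each window of 4 inside that interval held Dynlt1b, which at 0.478 lay just under the limit of 0.5. The other genes of the interval lay from 0.719 to 0.872.

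Long transcripts were lower and short transcripts higher at 22 than at 18 months, with Spearman's rho of fold change and length of -0.496 across 14853 genes, which are not independent replicates. Depth and a few abundant genes were argued against, since rho was -0.484 after thinning all libraries to 1 depth and -0.492 without the 500 most abundant genes. The ribosomal list lay at the 99th percentile of random lists matched on length, GC content and level (median 0.267, upper bound of the matched lists 0.261). With a closer match it lay at 98.46 (upper bound 0.264). The respiratory list lay at 99.78 and 99.74. In both lists the trend may account for most of the rise, as the matched medians were 0.213 and 0.193. Whether it was the whole cause cannot be decided from these percentiles. Members of each list varied together (estimated correlation of residuals 0.635 for ribosomal and 0.55 for respiratory members). Random lists need not do so, and their spread may be too narrow. The age of the mice and a difference between the 22-month libraries and the rest, such as in RNA quality or library preparation, cannot be told apart (rho of -0.496), since all 3 libraries of that age had slopes from -0.439 to -0.378 against -0.091 to 0.317 in the other 9, and an effect of age itself stays open as untested.

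The Tmem181 and Dynlt1 genes on chromosome 17 rose together at 22 months. A copy number difference between the mice cannot be told apart from a change in expression, since the interval was chosen because its genes rose, so that the lower values of its neighbours (highest 0.315) decide nothing, and reads shared within each family could spread a change of 1 copy over several genes. Age cannot be told apart from the origin of the mice, since the median of the 6 genes was -0.153 at 18 against 2 months and this series holds 1 set of libraries at 22 months. For Ide and Fgfbp3 on chromosome 19 (36917550 to 37334544), which rose by 0.99 and 0.90, a copy number difference of 1 unbroken interval that holds both was argued against, since 4 of the 5 genes between them lay from -0.188 to 0.082 (median of the 5, 0.002), while 4931408D14Rik had 2.605 ± 0.81. Ide had 741, 767 and 739 normalised counts in the 22-month libraries against 364 to 398 at 18 months and 367 to 812 at 6 months. At 6 months, replicate 2 was highest in Ide (812) and in Btaf1 (897), which lies between Fgfbp3 and Ide, and replicate 1 in Fgfbp3 (69.3). At 2 months, replicate 1 was highest in both Ide (544) and Fgfbp3 (76.1). Within ages, Pearson's r with Ide was 0.709 for Fgfbp3 (permutation p = 0.0818, adjusted 0.491), and 0.808 without the 2 farthest libraries. For Btaf1 these values of r were 0.624 and 0.258. Separate copy number changes and an effect of age on these genes stay open as untested.

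Interferon-stimulated genes were higher at 22 than at 2 months. The list's median exceeded that of the microglia markers by 1.167 (95% bootstrap interval 0.557 to 1.647), and by 0.512 (0.065 to 0.937) without 22 months replicate 1. For these libraries, this argued against a higher share of microglia as the whole cause. Members of a list are not independent and the interval does not measure the spread between mice, so such a cause is not excluded. 22 months replicate 1 alone was also argued against, since 14 of 24 genes were higher without it (median 0.918), although Oasl2 had 849 normalised counts in that library against 119 and 77.7 in the others of its age. A response to interferon that comes with age remains a hypothesis and was not tested, and infection or housing of the mice is not given by the labels.

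Other splits of the same samples were counted for each comparison. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split alone, 1 of 10, reached its number of genes in each of the 6 comparisons, with 145 against a highest other of 0 at 6 against 2 months, 24 against 1 at 18 against 6 months, 2956 against 0 at 22 against 18 months, 5584 against 1 at 22 against 2 months, 1141 against 0 at 18 against 2 months and 3480 against 0 at 22 against 6 months. For the list tests, as many lists passed in 6 of 10 splits at 6 against 2 months (8, highest other 9), in 2 at 18 against 6 months (13, 18), in 1 at 22 against 18 months (12, 10), in 1 at 22 against 2 months (18, 15), in 4 at 18 against 2 months (12, 14) and in 1 at 22 against 6 months (14, 11). For any age, 1 of 100 drawn splits, the real one, gave as many genes (4936, highest other 2554), which argued against a random sorting of these libraries. As the libraries of an age may be technical, it cannot exclude chance differences between single mice or between sets of libraries. For turns at 18 months, 3 of 100 gave at least as many (5), and the highest other split gave 1887. The drawn splits mix libraries that differ between ages, so this share does not measure chance and decides nothing. The cause of the 1887 was not tested. For turns at 6 months all 100 gave at least the real count of 0 (highest other 15), which decides nothing.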
